A study of Mus musculus with 12 samples.

How the data were processed

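RNA of splenocytes from DBA/2 mice aged 10 weeks was measured on 12 single-colour arrays after 9 days of coculture, with interleukin-2 added every 3 days, per the labels' protocols. Biotin-labelled cRNA was made from 6 µg of total RNA, per the labels' protocols. The deposited values are an intensity per probe set on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The mean of each array, trimmed of the lowest and highest 2% of probe sets, was 500 in the deposited intensities, so each array had been scaled by a single factor. Scanner files and detection calls were not used here, and the number of arrays limits the precision.

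The table held 45101 probe sets, of which 64 were controls. Of the other 45037, 34945 named 1 gene in the platform annotation, 932 named several and 9160 were not listed there. Only probe sets with 1 gene were named. Gene identifiers of 34754 of them were found in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. That table served for gene names only, and no coordinates are given.

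All choices of test, groups, gene lists, filters and alternatives were fixed before the data were examined, except those named as later. Among the array measures, the 3'/5' ratios of pyruvate carboxylase and the transferrin receptor were not fixed in advance. Signals were transformed as log2(signal + 16), so that changes of dim genes are understated. Since the array medians differed by a factor of 1.26, above the fixed limit of 1.25, arrays were quantile normalized. Probe sets above the median of their own array on at least 3 arrays were kept, which left 24366, and for each gene the one with the highest mean was used, giving 11325 genes of 18193 named on the array. Each gene was fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays with 1 mean per group and a trended prior in eBayes (8 residual and 5.14 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg at 0.05. The median standard error was 0.153 on the log2 scale, and the median 95% interval reached 0.33 to each side, or 0.467 for the interaction. SEMA6A, SEMA3A and the group with both factors were each compared with the control, both factors with each alone, and the interaction was tested.

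Of 35 gene lists, 32 with at least 5 tested members were tested with camera at a preset correlation of 0.01. The lists of alternative macrophage, erythroid and fibroblast genes had 3, 2 and 4 tested members and were not tested. None of the camera calls held with an estimated correlation. Fry, added after the data were seen, tests whether a list's genes move on balance one way and called none. Counts adjusted over the list alone take only a list's members into the adjustment. Cell type lists describe RNA that moves together in a mixed culture, not counted cells.

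As no comparison had 5 genes past the threshold, the genes named are the 5 with the smallest p in each direction per comparison, given as values that did not pass, up to 4 members past the threshold per list described, and a fixed panel of semaphorin, receptor, cytokine, T cell, macrophage and keratin genes. Symbols of clones and predicted genes and receptor or immunoglobulin segments were left out. Other list members named as examples were chosen after their values were seen.

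Single values were compared by 2-sided exact permutation over all 924 splits of 12 arrays into 6 and 6 (either factor alone against neither or both was added after the data were seen), with Python 3.11.15 and numpy 2.4.6. The alternatives were no further normalization, pseudocounts of 1 and 64, no filter or the 75th percentile, the probe set with the largest interquartile range, every probe set counted, only the arrays compared, a replicate block, no prior trend, array weights, a 2-fold minimum and leaving out each array. The planned estimate of the array weights stopped before it converged, so a gene by gene estimate was added after the data were seen.

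The test was tested on simulated data with the real means and spreads of the 11325 genes and 200 genes changed in SEMA6A against control, in 20 draws. It recovered 43.0% of genes changed 1.5-fold, 75.8% of those changed 2-fold and 95.6% of those changed 4-fold, with 4.83% false calls. A list of cell cycle genes raised by 0.5 was called in 20 of 20 draws, and 1 other list was called over all draws. The simulated genes vary independently, which the real ones need not.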

Results

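Gene expression was measured in mouse splenocytes after 9 days of coculture with KLN-205 cells, a mouse squamous carcinoma line of the lung. The tumour cells carried a knockdown of SEMA3A, a secreted semaphorin that binds neuropilin and plexin receptors, and interleukin-2 was present at 100 units/mL. In the control group nothing more was added. In the SEMA6A group the tumour cells overexpressed SEMA6A, a transmembrane semaphorin. In the SEMA3A group purified SEMA3A protein was added at 10 µg/mL, and the remaining group received both. Each of the 4 groups had 3 arrays, 12 in all. The median signal of an array lay between 42.5 and 53.5 and the highest signal between 44046 and 53212. The labels do not say whether the arrays of a group came from separate cultures or animals, so p-values here measure only the spread between these samples.

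Genes of cytotoxic T cells gave high signals in these cultures. Gzmb, the granzyme B gene of cytotoxic granules, was at a signal of 43120 ± 4872 (SD, n = 3) in the control group, near the highest signal on these arrays. Prf1, which encodes perforin, was at 14420 ± 1503, the proliferation marker Mki67 at 9240 ± 521 and Cd8a at 3114 ± 682 (SD, n = 3 each). Cd4, at 6.03 ± 2.31, Foxp3, at 18.5 ± 1.98, and the macrophage marker Adgre1, at 26.6 ± 12.5, lay below the filter on dim probe sets. Krt14, a keratin of squamous epithelium, was below it too, at 17.6 ± 10.9. Signals of different probe sets are not on a common scale of RNA amount.

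The manipulated genes gave no usable signal in this RNA. All 3 probe sets of Sema3a and all 3 of Sema6a stayed below the filter, with signals of at most 51.3 and 44.6 on any array. Sema6a was at 17.0 ± 11.9 in the control group and 18.6 ± 13.6 in the SEMA6A group (SD, n = 3 each). The arrays were of splenocyte RNA, so these values do not check the overexpression in the tumour cells. They were planned as a check of tumour cell RNA carried over, which signals below the filter cannot decide. Among the receptors, all 4 probe sets of Nrp1 passed the filter, and its brightest was at 91.3 ± 10.2 in the control group. Plxna1, Plxna3 and Plxna4 passed with 1 probe set each, at 86.4, 52.3 and 56.4 in the control group. Nrp2 and Plxna2 did not pass, so they were not among the tested genes. With both factors against control, the 4 probe sets of Plxna2 had log2 differences of 0.86, 0.69, 0.23 and 0.04. None passed when adjusted over all probe sets. The first was at a signal of 10.8 in the control group and 37.4 with both factors. Signals below the filter cannot decide whether Plxna2 changed. No receptor that passed the filter changed in any comparison. Among the tested probe sets, 1 per gene, the largest difference was that of Plxna1 with both factors against SEMA3A alone, at a log2 difference of 0.66 ± 0.25 (SE; limma adjusted p = 0.40). The list of 25 tested semaphorins, plexins and neuropilins was called in no comparison.

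RNA quality set 1 array apart. SEMA6A replicate 2 had a 3'/5' signal ratio of 1.22 for the Gapdh control probe sets, against 0.767 to 0.818 on the others. Its ratio for Actb was 1.23, for pyruvate carboxylase 15.5 and for the transferrin receptor 35.7, the highest in each case. The transferrin receptor ratio was 20.04 ± 9.04 on the 6 arrays with either factor alone and 8.99 ± 2.45 on the 6 with neither or both (SD; 2-sided exact permutation p = 0.0108, adjusted p = 0.0758 over 7 array measures). The pyruvate carboxylase and transferrin receptor ratios were not among the measures fixed in advance. Over all 14 tests of array measures against the SEMA6A factor or the SEMA3A factor, these ratios included, no adjusted p was under 0.05. The lowest was for the pyruvate carboxylase ratio, at 5.67 ± 1.05 on the 6 arrays with SEMA3A and 9.29 ± 3.29 on the 6 without it (2-sided exact permutation p = 0.0043, adjusted p = 0.0606). The squamous carcinoma list, whose genes mark epithelial tumour cells, had a mean log2 level of 7.40 ± 0.24 with SEMA6A and 7.27 ± 0.20 without (SD, n = 6 each; exact permutation p = 0.32). On the arrays with either factor alone it was at 7.46 ± 0.26, and on those with neither or both at 7.21 ± 0.06 (exact permutation p = 0.0498, adjusted p = 0.1742). With 3 arrays against 3 the smallest exact p is 0.1.

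**Figure D1:**
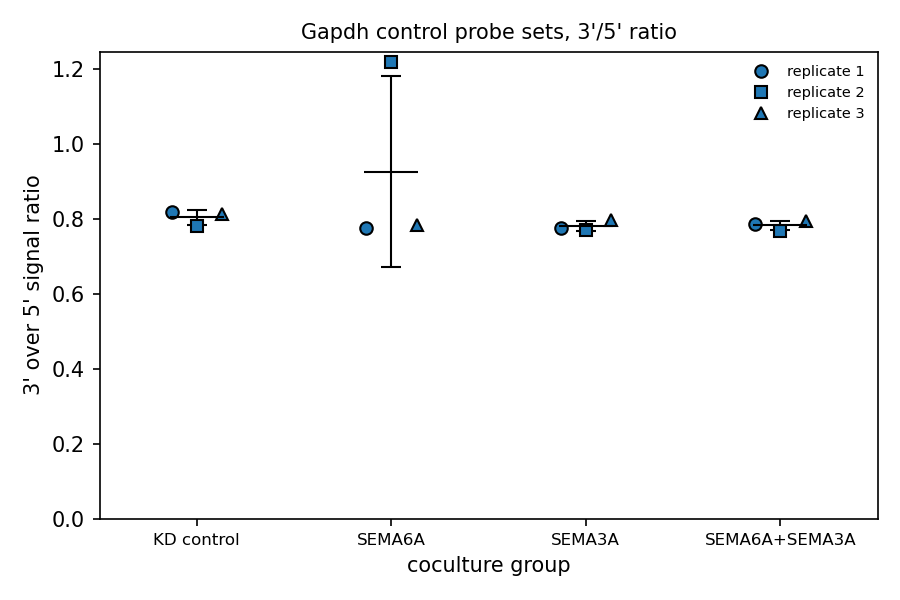
The 3'/5' signal ratio of the Gapdh control probe sets (vertical axis, a ratio without unit) for each array, by coculture group, with the group mean and SD (n = 3). SEMA6A replicate 2 lies at 1.22 and the other 11 arrays between 0.767 and 0.818.

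The first comparison asked what SEMA6A on the tumour cells changed without added SEMA3A. The glycolysis and hypoxia list rose: all 26 tested members were above 0, with a mean log2 change of 0.50 (camera adjusted p = 2.03e-11; adjusted p = 0.844 with an estimated correlation). Of its members, 16 passed when adjusted over the list alone and 0 when adjusted over all genes. They included Bnip3, a mitophagy gene induced by low oxygen, at 0.64 ± 0.18 (SE), and Egln3, an oxygen-sensing hydroxylase, at 1.00 ± 0.27. Pfkl, of the phosphofructokinase step, was at 0.75 ± 0.22 and the glycolytic enzyme Tpi1 at 0.52 ± 0.14. Hif1a itself was at 0.01 ± 0.10. The arrays of the group differed: SEMA6A replicates 2 and 3 lay at 0.498 and 0.313 around the mean of all arrays, while replicate 1 lay at -0.127 and the control arrays at -0.353 to -0.213. Replicate 2 was the array with the Gapdh ratio of 1.22, and without it the mean change was 0.37. The transferrin receptor 3'/5' ratio was 8.39, 35.7 and 23.3 on SEMA6A replicates 1 to 3, against 6.82 to 9.34 on the control arrays. The squamous carcinoma list lay at -0.006, 0.441 and 0.273 on the same replicates and had a mean change of 0.38 (camera adjusted p = 0.0721).

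Immune genes gave values that did not pass. Pdcd1, which encodes the inhibitory receptor PD-1, was at 638 ± 190 in the SEMA6A group and 282 ± 58.3 in the control group (SD, n = 3 each), a log2 difference of 1.11 ± 0.34 (SE; limma adjusted p = 0.48). The inhibitory receptor gene Lag3 was at 1.32 ± 0.43 and Ctla4 at 0.99 ± 0.41, while Cd274, of the same list, was at -0.29 ± 0.13 (adjusted p = 0.48). Ifng, the interferon-gamma gene, was at 340 ± 98.5 against 541 ± 2.34, a log2 difference of -0.69 ± 0.22 (adjusted p = 0.48). The cytokine genes Csf2 and Lta were at -1.33 ± 0.56 and -1.03 ± 0.38, while Il10, of the same list, was at 0.69 ± 0.32 (adjusted p = 0.48 each). Gzmb, at 0.07 ± 0.06, and Prf1, at 0.11 ± 0.16, had 95% intervals from -0.05 to 0.19 and from -0.23 to 0.44. The genes with the smallest p were Slc5a5, which encodes the sodium and iodide symporter, at -1.41, Scyl2, at -0.89, Mynn, at -0.61, Mier3, at -0.63, and Ankrd9, at -1.16, and on the other side Mboat2, at 0.96, Gtf2ird2, at 0.56, Irgq, at 0.94, Bmerb1, 2.38-fold higher, and Cd24a, at 1.69 (limma adjusted p = 0.48 for each). With the probe set of largest interquartile range, Mynn was at 0.08, the other direction. Scyl2 was at -0.60 with the array weights that did not converge and at -0.63 with the gene by gene estimate. With pseudocounts of 1 and 64 the dim genes Slc5a5 and Ankrd9 were at -2.05 and -0.74 and at -1.68 and -0.61, and Cd24a was at 1.02 with 64.

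By limma, 0 of 11325 genes changed, with 1184 at an unadjusted p under 0.05 where chance gives 566, and a lowest adjusted p of 0.475. The count at an unadjusted p under 0.05 was 557 without SEMA6A replicate 2 and 3016 without SEMA6A replicate 1, where 503 genes passed after adjustment, and with weights for each array 260 passed by the estimate that did not converge and 0 by the gene by gene estimate. Fry, which tests each list alone, called 0 of 32 lists.

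**Figure D2:**
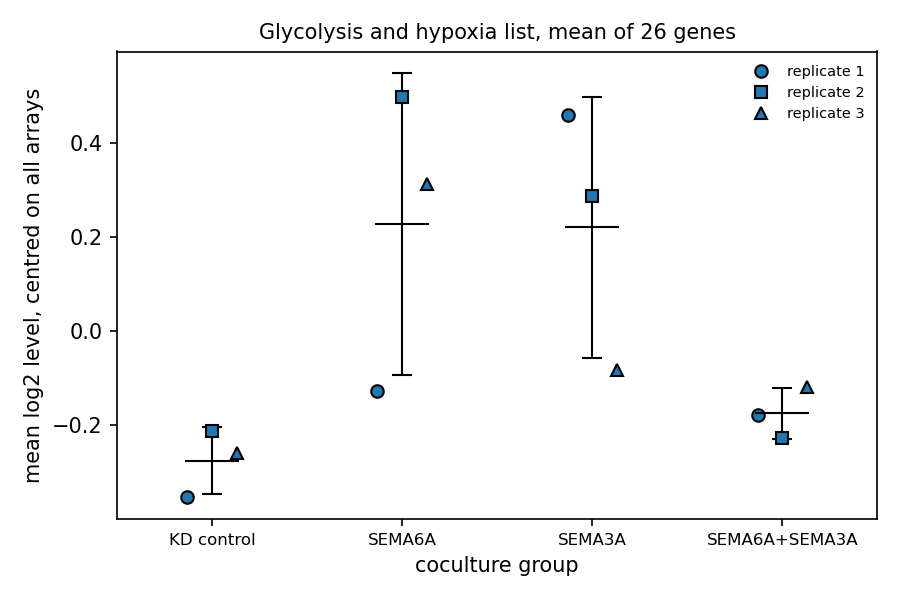
Mean log2 level of the 26 tested genes of the glycolysis and hypoxia list (vertical axis, centred on the mean of all 12 arrays) for each array, by coculture group, with the group mean and SD (n = 3). SEMA6A replicates 2 and 3 and SEMA3A replicates 1 and 2 lie between 0.287 and 0.498, and the other 8 arrays between -0.353 and -0.083.

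The second comparison asked what purified SEMA3A changed without SEMA6A. Genes of the glycolysis and hypoxia list rose here too, with 25 of 26 members above 0 and a mean log2 change of 0.50 (camera adjusted p = 9.02e-13; adjusted p = 0.655 with an estimated correlation). When adjusted over the list alone, 17 members passed, and 0 over all genes. Among them were Bnip3, at 0.70 ± 0.18 (SE), the aldolase gene Aldoc, at 1.37 ± 0.42, P4ha1, a collagen prolyl hydroxylase, at 0.61 ± 0.17, and the pyruvate kinase gene Pkm, at 0.46 ± 0.13. SEMA3A replicates 1 and 2 lay at 0.459 and 0.287 and replicate 3 at -0.083. The transferrin receptor 3'/5' ratio was 17.2, 17.6 and 18.1 on these arrays, against 6.82 to 9.34 on the control arrays, and the squamous carcinoma list lay at 0.124, 0.208 and -0.305.

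Of the other lists, 3 were called. The macrophage and monocyte list had 9 of 30 members tested and the mast cell and basophil list 5 of 16. Most of their other members lay below the filter. The macrophage and monocyte list had 8 of 9 members above 0 and a mean of 0.37 (camera adjusted p = 0.0375; adjusted p = 0.655 with an estimated correlation). Of these, only Fcgr3, an Fc receptor gene, passed when adjusted over the list alone, at 1.07 ± 0.28 (SE). The mast cell and basophil list had all 5 members above 0 and a mean of 0.38 (camera adjusted p = 0.0375; adjusted p = 0.705 with an estimated correlation), and Kit, the stem cell factor receptor gene, passed over the list alone at 0.67 ± 0.19. The list of T cell receptor signalling and immediate early genes had 17 of 22 members below 0 and a mean of -0.12 (camera adjusted p = 0.0375; adjusted p = 0.705 with an estimated correlation), with 0 members past the list alone. These 3 calls were lost when dim probe sets were kept, with means of 0.07, 0.22 and -0.10 and adjusted p = 0.726, 0.112 and 0.112. Without single arrays the macrophage call was lost for control replicate 3 (adjusted p = 0.0531) and SEMA3A replicates 1 and 2 (0.146 and 0.0717), the mast cell call for control replicates 1 and 2 (0.113 and 0.0518) and SEMA3A replicate 1 (0.276, with a mean of 0.19), and the T cell receptor call for control replicates 1 and 3 (0.107 and 0.0531) and SEMA3A replicates 2 and 3 (0.0637 and 0.067).

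Of single genes, Ifng was at 389 ± 126 (SD, n = 3), a log2 difference of -0.52 ± 0.22 (SE; limma adjusted p = 0.56), and Pdcd1 at 527 ± 282, a difference of 0.72 ± 0.34 (adjusted p = 0.57). Cd274, of the inhibitory receptor list with Pdcd1, had a difference of -0.32 ± 0.13 (adjusted p = 0.55). The replication helicase gene Mcm6 was at 0.61 ± 0.13 and passed when adjusted over the cell cycle list alone (adjusted p = 0.01). Other genes with small p were Nsg2, at -0.92, the cyclin E2 gene Ccne2, at -0.82, Hells, at -0.46, the replication nuclease gene Fen1, at -0.48, Tnfsf8, at -0.94, Gzf1, at 0.59, Fam162a, at 0.58, Zfp825, at 0.61, and Cert1, at 0.39 (limma adjusted p = 0.55 for each). With the probe set of largest interquartile range, Cert1 was at -0.69, the other direction, and Fen1 at -0.31. By limma 0 genes changed, with 990 at an unadjusted p under 0.05 and a lowest adjusted p of 0.551. The count at an unadjusted p under 0.05 was 412 without SEMA3A replicate 1 and 1745 without SEMA3A replicate 3. Fry called 0 of 32 lists.

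The third comparison set both factors together against the control. The glycolysis and hypoxia list had 20 of 26 members above 0 and a mean of 0.10, and was not called (camera adjusted p = 0.384). Egln3 was at 0.29 ± 0.27 (SE), Bnip3 at 0.09 ± 0.18, Ldha at 0.00 ± 0.07 and Slc2a1, the glucose transporter gene, at 0.13 ± 0.23. Ifng was at 642 ± 47.6 (SD, n = 3) against 541 ± 2.34 in the control group, a difference of 0.26 ± 0.22 (limma adjusted p = 1). Mcm6 was at 0.67 ± 0.13 and passed when adjusted over the cell cycle list alone (adjusted p = 0.0045), not over all genes (limma adjusted p = 0.51). Erdr1 was at -1.25 ± 0.21 and Klhl17 at 0.61 ± 0.11 (adjusted p = 0.51 each). Acta1, at -1.77, Mfsd4b4, at -1.06, Tmem267, at -1.01, Dusp5, at -0.46, Zfp825, at 0.67, Vars2, at 0.83, and Rgs1, at 0.56, had higher adjusted p, from 0.79 to 0.95. With pseudocounts of 1 and 64 the dim gene Acta1 was at -2.70 and -0.91, and with 64 Mfsd4b4 was at -0.67. By limma 0 genes changed, with 465 at an unadjusted p under 0.05, fewer than the 566 that chance gives. Camera and fry each called 0 of 32 lists, and camera called 1 without replicate 2 of the group with both factors. After adjustment 1 gene passed without SEMA6A replicate 1 (Mcm6) and 1 without SEMA3A replicate 3 (Erdr1). The count at an unadjusted p under 0.05 was 294 without control replicate 3 and 771 without SEMA6A replicate 2.

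The fourth comparison asked what SEMA6A changed where SEMA3A was present. Here the glycolysis and hypoxia list fell, with 24 of 26 members below 0 and a mean log2 change of -0.40 (camera adjusted p = 3.84e-08; adjusted p = 0.475 with an estimated correlation). When adjusted over the list alone, 6 members passed, among them Pkm, at -0.47 ± 0.13 (SE), P4ha1, at -0.59 ± 0.17, Bnip3, at -0.61 ± 0.18, and Pgk1, at -0.25 ± 0.07. The transferrin receptor 3'/5' ratio was 5.93 to 12.2 on the arrays with both factors, against 17.2 to 18.1 with SEMA3A alone. The type I interferon response list rose, with 17 of 25 members above 0 and a mean of 0.24 (camera adjusted p = 0.0106; adjusted p = 0.475 with an estimated correlation). None of its members passed over the list alone. Cmpk2 was at 0.76 ± 0.26 and Ifit2 at 0.41 ± 0.15. The neutrophil list, with 5 of 19 members tested, fell. All 5 were below 0, with a mean of -0.63 (camera adjusted p = 0.0431, or 0.475 with an estimated correlation). Among them Il1r2, the decoy receptor gene of interleukin-1, was at -1.09 ± 0.49. The neutrophil call was lost without further normalization (adjusted p = 0.0613), with dim probe sets kept (0.506, with a mean of -0.11), without SEMA6A replicate 2 (0.0555) or 3 (0.0504), without SEMA3A replicate 1 (0.0989) and without replicate 1 (0.0686) or 3 (0.0745) of the group with both factors. The interferon call was lost without SEMA3A replicate 1 (adjusted p = 0.0989, with a mean of 0.15) and without replicate 2 of the group with both factors (0.0707).

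Ifng was 0.77 ± 0.22 (SE) higher on the log2 scale and passed when adjusted over the helper T cell cytokine list alone (adjusted p = 0.044), not over all genes (limma adjusted p = 0.40). The genes with the smallest p were Cpox, of haem synthesis, at 1.53, Nsg2, at 0.96, Cycs, the cytochrome c gene, at 0.47, and Tra2a, at 0.51 (limma adjusted p = 0.29 each). Qrsl1, at 0.55, Lgals8, at -0.51, Spop, at -0.45, Clic4, at -0.46, Hoxa9, at -1.50, and Rnf130, at -0.41, followed (adjusted p = 0.40 each). The probe set of largest interquartile range put Rnf130 at 0.59, the other direction, Qrsl1 at 0.22 and Spop at -0.91. With pseudocounts of 1 and 64 the dim gene Hoxa9 was at -2.22 and -0.77. By limma 0 genes changed, with 1270 at an unadjusted p under 0.05 and a lowest adjusted p of 0.29. The count at an unadjusted p under 0.05 was 589 without SEMA3A replicate 1 and 2038 without SEMA3A replicate 3. With weights for each array 624 passed by the estimate that did not converge and 284 by the gene by gene estimate. Fry called 0 of 32 lists.

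The fifth comparison asked what SEMA3A changed where the tumour cells carried SEMA6A. Again the glycolysis and hypoxia list fell, with 25 of 26 members below 0 and a mean of -0.40 (camera adjusted p = 4.33e-08; adjusted p = 0.669 with an estimated correlation). Without SEMA6A replicate 2, the array with the Gapdh ratio of 1.22, the mean was -0.27 (camera adjusted p = 1.15e-05). The squamous carcinoma list had a mean of -0.34 (camera adjusted p = 0.0688), and the transferrin receptor 3'/5' ratio was 5.93 to 12.2 with both factors, against 8.39, 35.7 and 23.3 with SEMA6A alone. Of the members of the glycolysis and hypoxia list 0 passed over the list alone, where the lowest adjusted p was 0.0534. Ifng was 0.95 ± 0.22 (SE) higher and passed when adjusted over the helper T cell cytokine list alone (adjusted p = 0.01), not over all genes (limma adjusted p = 0.42). Pdcd1 was at -0.88 ± 0.34 and Lag3 at -1.26 ± 0.43 (limma adjusted p = 0.42 for Pdcd1), while Cd274 was at 0.06 ± 0.13. Slc5a5 had the smallest p, at 1.55 ± 0.24 (adjusted p = 0.26). Dnajb12, at 0.87, Scyl2, at 0.82, Anp32b, at 0.35, Lypla1, at 0.50, Erdr1, at -1.13, Fyttd1, at -0.57, Cercam, at -0.97, and Acta1, at -1.59, followed, as did Spag1, which was 2.00-fold lower (adjusted p = 0.42 each). The probe set of largest interquartile range put Lypla1 at -0.11 and Fyttd1 at 0.48, the other direction for both. With pseudocounts of 1 and 64 Slc5a5 was at 2.22 and 0.82 and Acta1 at -2.48 and -0.79. Scyl2 was at 0.52 with the array weights that did not converge and at 0.55 with the gene by gene estimate. By limma 0 genes changed, with 1304 at an unadjusted p under 0.05 and a lowest adjusted p of 0.257. The number that passed was 369 without SEMA6A replicate 1, 369 with array weights that did not converge, 6 with the gene by gene estimate and 1, Slc5a5, without the trend in the prior. At an unadjusted p under 0.05 there were 709 genes without SEMA6A replicate 2 and 2960 without SEMA6A replicate 1. Fry called 0 of 32 lists.

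**Figure D3:**
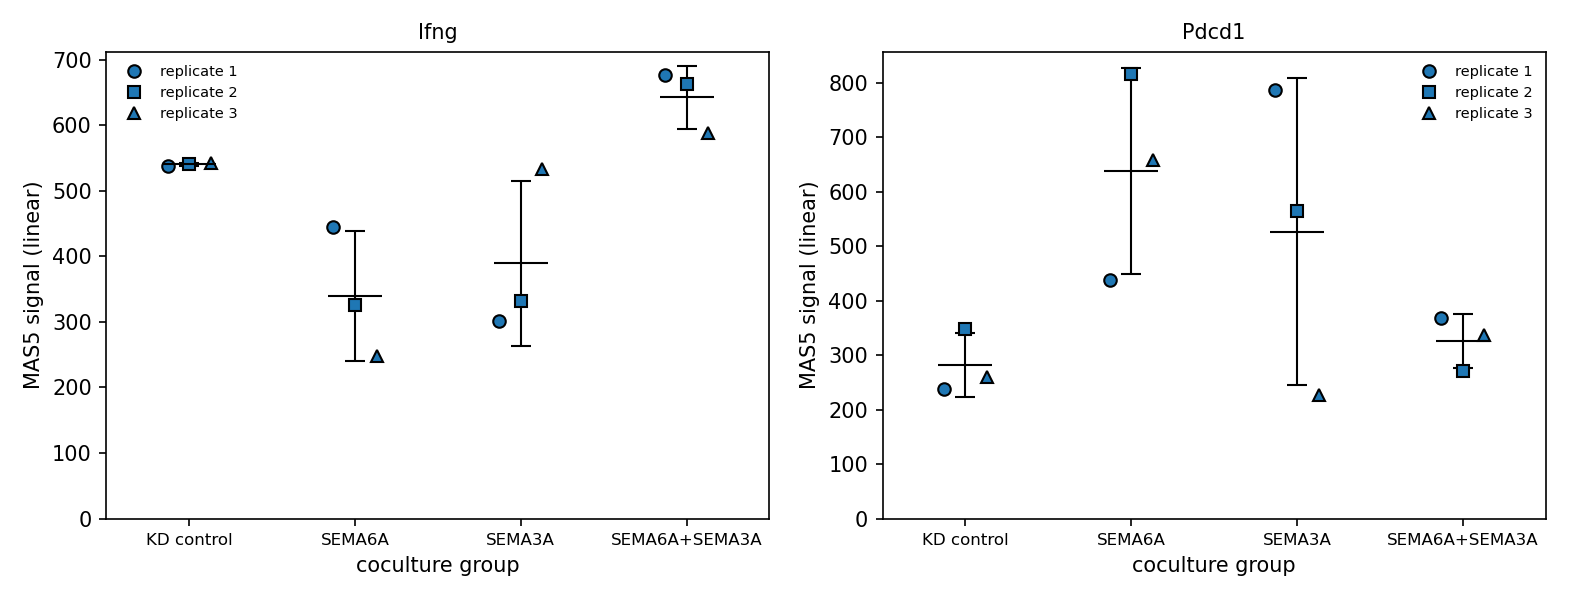
Signal of Ifng (left) and Pdcd1 (right) on each array (vertical axes, linear MAS5 signal from 0), by coculture group, with the group mean and SD (n = 3). Ifng lies between 538 and 543 on the control arrays and between 588 and 677 with both factors, while the single-factor groups spread from 248 to 534.

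The interaction asked whether the SEMA6A effect differed with and without SEMA3A. In the glycolysis and hypoxia list it was negative in all 26 members, with a mean of -0.90 on the log2 scale (camera adjusted p = 2.68e-13; adjusted p = 0.639 with an estimated correlation). When adjusted over the list alone, 21 members passed, and 0 over all genes. P4ha1 was at -1.08 ± 0.24 (SE), Bnip3 at -1.24 ± 0.25, Egln3 at -1.65 ± 0.38 and Pfkl at -1.27 ± 0.31. The transferrin receptor 3'/5' ratio was 20.04 ± 9.04 with either factor alone and 8.99 ± 2.45 with neither or both (SD, n = 6 each), and the squamous carcinoma list had an interaction of -0.49 (camera adjusted p = 0.198). The cell cycle list had a positive interaction, with 24 of 33 members above 0 and a mean of 0.20 (camera adjusted p = 0.0264; adjusted p = 0.639 with an estimated correlation). None of its members passed over the list alone. The replication genes Mcm2, at 0.66 ± 0.22, and Rrm2, at 0.55 ± 0.17, were above 0 and Mki67, at -0.29 ± 0.11, below. The cell cycle call was lost without control replicate 2 (adjusted p = 0.0635), SEMA6A replicate 2 (0.0854, with a mean of 0.12), SEMA3A replicate 1 (0.0803) or replicate 3 of the group with both factors (0.0517).

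When adjusted over the helper T cell cytokine list alone, Ifng passed at 1.46 ± 0.32 (SE; adjusted p = 0.0048), as did Lta at 1.92 ± 0.54 (0.018) and Csf2 at 2.51 ± 0.79 (0.024). Il10, of the same list, was at -0.76 ± 0.45 and did not pass. These are some of the 48 members that passed over their own lists in the interaction, counted once per list. Others were Cd6, at 2.33, and Cd3e, at -0.59, of the T cell core, Ccr7, at 1.91, Cd44, at 1.58, and Klf2, at -1.22, of naive and memory T cells, Batf3, at 1.61, of dendritic cells, Fcgr3, at -1.44, of macrophages and monocytes, and Il1r2, at -2.21, of neutrophils. Over the inhibitory receptor list alone, Lag3 passed at -2.30 ± 0.61, Ctla4 at -1.89 ± 0.58 and Pdcd1 at -1.60 ± 0.48 (adjusted p = 0.03 each). Cd274, of the same list, was at 0.37 ± 0.19 and did not pass. As a whole the cytokine list, with a mean of 0.52 and a median of 0.09, and the receptor list, with a mean of -0.55, were not called (camera adjusted p = 0.324 and 0.187), and none of these genes passed over all genes. The genes with the smallest p were Nsg2, at 1.43, Slc5a5, at 1.94, Scyl2, at 1.16, Ccne2, at 1.33, and Cycs, at 0.59, and with negative values Irgq, at -1.56, Higd1a, at -0.69, Bnip3, at -1.24, Akr1b10, at -1.17, and Idh1, at -1.33 (limma adjusted p = 0.20 each). With pseudocounts of 1 and 64 Slc5a5 was at 2.72 and 1.06. By limma 0 genes passed, with 2037 at an unadjusted p under 0.05 and a lowest adjusted p of 0.197. The number that passed was 1260 without SEMA6A replicate 1, 258 without SEMA3A replicate 3, 2117 with array weights that did not converge and 1569 with the gene by gene estimate. At an unadjusted p under 0.05 there were 1304 genes without SEMA3A replicate 1 and 3392 without SEMA6A replicate 1. Fry called 0 of 32 lists.

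The SEMA6A and SEMA3A effects were set against each other over all genes, which are not independent replicates. Their log2 changes correlated at r = 0.691, where unchanged groups simulated against the same 3 control arrays gave 0.502 (0.476 to 0.531 in 100 draws). The covariance was 0.0489 against 0.0246 simulated, a difference of 0.0242. Leaving out 1 array gave r from 0.577 to 0.734, a wider range than that of the draws. The difference from the simulated value was therefore not tested against the spread between arrays. The 3 control arrays are too few to give each effect its own controls.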

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

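The tests of the array with a low 5' signal, of RNA quality, of tumour RNA and of differences between cultures were chosen only after the result was seen. The glycolysis and hypoxia list is listed here because its interaction passed a test, with a mean of -0.899, as is the cell cycle list, with a mean of 0.202.

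In the first pattern the list was higher with either factor alone than with neither or both. The shift was -0.91 without further normalization and -0.76 without SEMA6A replicate 2, the array with the low 5' signal, which argues against either as the whole cause, but RNA quality over all arrays stays open: the transferrin receptor 3'/5' ratio was higher with either factor alone (exact permutation p = 0.0108, adjusted p = 0.0758), while the Gapdh ratio had p = 0.8961. RNA of the tumour cells may take part. The squamous carcinoma list had an interaction of -0.49 (exact permutation p = 0.0498, adjusted p = 0.1443). Its brightest genes Cdh1, Epcam and Itga6 had mean log2 levels of 10.36, 9.75 and 9.12 in the control group, with interactions of 0.29, -0.48 and 0.13. The keratin gene Krt14 had signals of 7.41 with SEMA6A and 13.5 with SEMA3A, against 17.6 in the control group and 28.8 with both. Sema6a was at 18.6 in the SEMA6A group and 17.0 in the control group. Both genes lay below the filter, so their values cannot decide the question. No array of tumour cells alone shows which genes they would bring. Differences between cultures that have nothing to do with the factors remain open too: exact permutation over the 924 splits gave p = 0.0043 and 0.1385 after adjustment over 32 lists, where a single list cannot go below 0.0693. An effect of the semaphorins stays among the open explanations. SEMA6A replicate 1, at -0.127, and SEMA3A replicate 3, at -0.083, lay above the control arrays but below the other arrays with a single factor. The arrays with both factors lay at -0.177, -0.227 and -0.119, a range that includes SEMA6A replicate 1.

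The second pattern was more genes at an unadjusted p under 0.05 than chance gives, in all comparisons but that of both factors against control, with 0 past adjustment by limma. For the interaction 2 of 100 drawn splits of the 12 arrays gave as many genes, the real split included. The real value was 2037 and the highest other 2410. This share lies under 0.05 but was not adjusted for the other split checks. It also takes the arrays as independent, which the labels do not say, so chance assignment of arrays is not excluded. The 10 splits of 6 arrays are too few for a share under 0.05: the real count and the highest other were 1184 and 1868 for SEMA6A against control (3 splits as large), 990 and 812 for SEMA3A (1), 465 and 523 for both factors (2), 1270 and 868 for both against SEMA3A (1), and 1304 and 1934 for both against SEMA6A (2).

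The third pattern was the number of lists called. For the interaction 54 of 100 splits gave at least the real number of 2 lists, and the highest other gave 7, so chance assignment was not excluded for the number of lists. In the other comparisons the splits are again too few, with real and highest other numbers of 1 and 3 for SEMA6A (8 of 10 splits as large), 4 and 8 for SEMA3A (5), 0 and 3 for both against control (10), 3 and 9 for both against SEMA3A (5), and 1 and 3 for both against SEMA6A (6).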

How the results depend on the processing

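Fry, the gene by gene array weights and leaving out arrays for the overlap of effects were chosen only after the result was seen. The count of changed genes was 0 in all 6 comparisons under no further normalization, other pseudocounts, no filter or a stricter one and every probe set. The 2-fold minimum only selects from the genes called in the main setting, which were 0, so it could give no other count. Where other settings moved a count, the cause was not tested. Array weights gave 260 genes for SEMA6A against control, 3 for both factors against control, 624 for both against SEMA3A, 369 for both against SEMA6A and 2117 for the interaction, from an estimate that stopped before converging; gene by gene weights gave 3, 284, 6 and 1569 for the last 4 and 0 for SEMA6A. Neither gave a gene for SEMA3A against control. Both weight SEMA6A replicate 2 lowest (0.197 and 0.217). For both factors against control, the probe set with the largest interquartile range gave 1 gene (Ywhab) and the fit of only the arrays compared gave 1 (Mcm6). For both against SEMA6A, the prior without trend gave 1 (Slc5a5).

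Leaving out each array gave 0 to 503 genes for SEMA6A, 0 to 0 for SEMA3A, 0 to 1 for both factors against control, 0 to 0 for both against SEMA3A, 0 to 369 for both against SEMA6A and 0 to 1260 for the interaction. The values of 503, 369 and 1260 came without SEMA6A replicate 1, the lowest array of its group on the glycolysis and hypoxia list; leaving out an array because of its values selects on the outcome, so these counts are no better estimate. Lists called ranged from 1 to 3, 2 to 6, 0 to 1, 1 to 9, 1 to 4 and 1 to 8 in the same order, and the correlation of effects from 0.577 (without SEMA6A replicate 2) to 0.734 (without control replicate 1), against 0.7 without further normalization.

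An estimated correlation and fry each left 0 lists in every comparison. Without the filter 1 list was called for SEMA3A, and without further normalization 2 for both against SEMA6A. The glycolysis and hypoxia list stayed called without each of the 12 arrays in all 5 comparisons that called it. The replicate numbers do not pair the arrays: same-numbered arrays had a mean residual correlation of -0.0652, with 1 of 18 pairs over 0.1, and 0 of 12 arrays correlated best with their own number. With the replicate block 0 genes passed in each comparison. Of 1347 values of the 60 named results, 1342 kept their direction, 5 did not and were not called (Mynn, Cert1, Rnf130, Lypla1 and Fyttd1, each with the probe set of largest interquartile range), 111 passed the threshold and 31, those 5 among them, turned or moved by at least the spread between replicates without passing. The count of kept directions says little, as the named genes were chosen for small p. A replicate block, no prior trend, only the arrays compared, or leaving out an array of another group also cannot change a log2 difference. Gzmb lies near the top of the signal range and Sema3a and Sema6a near its floor, which limits what changes can be seen in them.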

Other observations

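The tests of correlation with the glycolysis and hypoxia list and the exact permutation of list means were chosen only after the result was seen. Most lists were not called in the interaction. By their mean log2 values, the T cell core was at 0.25, cytotoxic effector genes at 0.13, naive and memory T cells at 0.18 with a median of -0.07, NK cells at 0.04 with a median of -0.26 and a downward test, regulatory T cells at -0.31, B cells at -0.20, plasma cells at -0.13 with a median of 0.01 and dendritic cells at 0.27. Macrophages and monocytes were at -0.47, inflammatory myeloid genes at 0.25, neutrophils at -1.13, mast cells and basophils at -0.46, megakaryocytes and platelets at 0.10, endothelial cells at 0.01 with a median of -0.02, type I interferon response at 0.32, antigen presentation at -0.02 with a median of 0.02 and the interferon-gamma response at 0.18. T cell receptor signalling was at 0.19, the IL-2 response at 0.05 with a median of -0.15 and a downward test, semaphorins, plexins and neuropilins at 0.03 with a median of -0.01 and a downward test, homing receptors at -0.43, cholesterol synthesis at -0.16, the unfolded protein response at -0.28, p53 and apoptosis at -0.07, ribosomal proteins at 0.03, oxidative phosphorylation at -0.04 and heat shock at 0.04. None of these was called by camera in the interaction.

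By exact permutation of list means, 11 of 32 lists had p under 0.05 for the interaction, 1 for the SEMA6A factor and 0 for the SEMA3A factor, and 0 passed after adjustment. The first principal component held 31.4% of the variance, with SEMA6A replicates 2 and 3 at 37.8 and 12.8, SEMA3A replicates 1 and 2 at 21.0 and 12.5 and the other 8 arrays below 0.

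On the glycolysis and hypoxia list the arrays fell into 8 low and 4 high, with a gap of 0.37, so no correlation over all 12 is given. A hypothesis was that the culture passes through a state, varying within groups, in which glycolysis genes and inhibitory receptors go up and helper cytokines go down. Among the 8 low arrays the inhibitory receptor list had r = -0.182 and rho = -0.19 (exact permutation p = 0.667 and 0.665, adjusted p = 0.905 and 0.966 over 31 lists), and r = 0.637 without the 2 farthest arrays. The helper T cell cytokine list had r = -0.324 and rho = -0.381 (exact permutation p = 0.434 and 0.36, adjusted p = 0.905 and 0.966), and r = -0.489 without the 2 farthest. Across the gap both lists separated the arrays: the 4 high arrays lay at 0.185 to 0.355 on the inhibitory receptor list and -0.318 to -0.129 on the helper T cell cytokine list, and the 8 low arrays at -0.235 to -0.088 and -0.016 to 0.279. The squamous carcinoma list separated them too, at 0.124 to 0.441 and -0.305 to -0.006, though not all its members moved so. Its bright genes Cdh1 and Itga6 had positive interactions, against the list mean. Other lists separated the arrays as well. The neutrophil list lay at 0.28 to 0.612 and -0.491 to -0.02, and the regulatory T cell list at 0.116 to 0.188 and -0.135 to -0.03. The macrophage and monocyte list lay at 0.083 to 0.343 and -0.182 to -0.039. The separation is thus not particular to the lists of the hypothesis. The hypothesis came from this separation, which therefore cannot test it, all 4 high arrays had a single factor, and the 8 low arrays span a narrow range, so it stays open.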
